A study of Rattus norvegicus with 20 samples.

How the data were processed

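Total RNA from the right ventricle of Wistar rats was sequenced 4 or 8 weeks after pulmonary banding or a sham operation, at an age of 7 or 11 weeks. Per the labels' protocols, the tissue was snap frozen, RNA was extracted with Trizol, its quantity was read on a Qubit and its quality on a Bioanalyzer, and libraries were made from 800 ng with the TruSeq Ribo-Zero Gold kit, which removes ribosomal RNA. The submitters' processing notes name STAR, DESeq2 and the genome build rn6, without versions. The program that counted the reads and its strand setting were not given in the sources used here.

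The authors deposited 1 table of normalized counts, a signal on the scale of reads divided by a size factor per library, for 18282 RefSeq transcript IDs in 19 libraries. The columns were matched to the labelled samples by group and replicate number. The labels list 20 samples, and the table had no column for replicate 2 of the 8-week banding group, which was not analysed here. Names of the deposited comparison tables state that the library GB20 was left out. The authors also deposited 6 tables of DESeq2 comparisons that hold a log2 fold change, a Wald statistic (a score, the log2 fold change over its standard error), a p-value and an adjusted p-value per ID. In 3 of the 6 deposited comparison tables the log2 fold change was found to run from the first named group minus the second, and in the others the reverse, by comparison with the group means, so every direction given here was set from the group means.

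In each library, 100% of the positive deposited values were whole multiples of 1 smallest step within 0.001, so read numbers could be recovered. The recovered totals ran from 2.70 to 8.54 M reads, with a median of 5.79 M. The spread between libraries of a group, not counting error alone, set the precision of every value given as a mean ± SD. Genes under the expression minimum were left out of the reported fit, and those with any reads entered the alternative with no filter.

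Of the 18282 IDs, 17351 took their symbol from a reference table of another rat assembly (GRCr8), used for names only, and 929 took it from the deposited comparison tables. No genome positions are given, because no annotation of rn6 was at hand. Genes with more than 1 ID numbered 586. A mean of at least 10 was reached by 13.0% of the IDs of such genes and by 61.7% of the IDs of genes with 1 ID, so genes with several transcripts were measured with fewer reads here and many fell below the minimum. Atp2a2 was measured through a single non-coding transcript ID and is uncertain. Values of near-identical copies, such as the hemoglobin genes, Mcpt1l1 and Ddit4l2, are uncertain for the same kind of reason, since reads can be split between copies. Without a stated strand setting, overlapping and antisense genes could not be told apart.

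The deposited normalized counts were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3, using an empirical Bayes fit with a trend, 2-sided, over IDs with a value of at least 10 in at least 4 libraries. This left 10926 IDs with 10881 symbols, called genes in the text. All 4 groups entered 1 model, so that they shared an estimate of the spread. There were 5 comparisons: banding against sham at 4 weeks and at 8 weeks, 8 against 4 weeks in sham and in banding, and the difference between both banding effects. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes, and are given ± SE. Group values are means ± SD.

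Gene lists were written from general knowledge and tested with limma's camera test at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over 145 tests (29 lists with at least 3 measured members, 5 comparisons), and again with a correlation estimated from the data. Beside each list stand the members that passed when adjusted over all genes and when adjusted over the list alone. A list of mitochondrially encoded genes had no measured member. The groups, the 5 comparisons, the lists, the test, its thresholds and most alternatives were fixed before the data were examined. Genes named in the text were also fixed by a rule: for each comparison, up to 5 called genes with the largest rise and 5 with the largest fall among those with a symbol, a mean of at least 50 and no overlap between the libraries of both groups (overlap was allowed for the difference of effects), the 3 members with the smallest limma p in each called list, and for both comparisons of banding with sham always Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Col1a1, Col3a1 and Postn. Of a list that was not called, up to 2 members with the smallest p could be named. Genes outside this rule are named as such.

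Alternatives were other pseudocounts (0.5 and 5), no filter, a minimum mean of 50, rescaling with edgeR's TMM factors, quantile normalization, the replicate number as a block, a robust fit, fits of only the groups compared, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and leaving out each library in turn. A score of atrial transcripts as a covariate (the mean log2 value of Myl7, Sln and Bmp10) and leaving out 7 libraries with a Myl7 value above 1000 were added after the data were seen. The fits were first tested on simulated counts with 200 changed genes and a smaller shift of the fatty acid oxidation list, whose members also counted as changed. Each gene was drawn on its own, without correlation between genes, so the shares below need not hold for the real fits. At 4 weeks (10824 genes) the fit recovered 77% of the genes changed 2-fold and 95% of those changed 4-fold, and 4.8% of its calls were false. At 8 weeks (10814 genes) these shares were 81%, 95% and 5.3%. For 8 against 4 weeks in sham (10829 genes) they were 82%, 95% and 5.2%, in banding (10827 genes) 71%, 94% and 4.7%, and for the difference of effects (10827 genes) 77%, 93% and 3.7%. The p-values measure the spread between samples. The labels number the samples of a group and say nothing more on the animals behind them. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.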

Results

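The data describe gene expression in the right ventricle, the chamber that pumps blood to the lungs, of young Wistar rats, an outbred laboratory strain. In pulmonary banding, a band narrows the pulmonary artery, so that the right ventricle pumps against a higher resistance, while a sham operation repeats the surgery without the band. RNA was sequenced from 5 ventricles each of sham at 4 weeks, sham at 8 weeks and banding at 4 weeks, and from 4 ventricles of banding at 8 weeks. Replicate 2 of the 8-week banding group was not analysed here. Recovered totals were 5.93 ± 0.807 M reads in sham at 4 weeks, 5.65 ± 1.73 M in sham at 8 weeks, 5.86 ± 1.46 M in banding at 4 weeks and 5.21 ± 2.56 M in banding at 8 weeks (mean ± SD). The shallowest libraries were replicate 1 of banding at 8 weeks with 2.70 M reads and replicate 1 of sham at 8 weeks with 2.81 M. Time after surgery went together with age, and the labels give no batch, so time, age and any day of collection could not be separated.

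The first question was how the right ventricle differs 4 weeks after banding. Of 14 measured transcripts known from the stretched and the fetal heart, 11 rose in banded ventricles. Nppb (NM_031545), which encodes the natriuretic peptide BNP, averaged 310.1 ± 177 normalized counts in sham (n = 5) and 4059.8 ± 851 in banding (n = 5), a log2 fold change of 3.95 ± 0.37 (limma, adjusted p = 1.16e-07). Myh7 (NM_017240), the slow myosin heavy chain of the fetal rodent ventricle, rose from 7812 ± 802 to 65216 ± 18541, by 3.02 ± 0.16 (adjusted p = 2.35e-11), and Myh6 (NM_017239), the fast adult chain, fell by 0.71 ± 0.12 (adjusted p = 0.000179). Quantile normalization fixes the Myh6 change at 0.00 here, since Myh6 is the highest ID in all 10 libraries and the highest ID is given the same value in each. In fatty acid oxidation, the main fuel pathway of the adult heart, 24 of 30 genes fell, and 10 of 16 macrophage markers rose.

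The largest rises among the genes that met the naming rule were those of Tceal7 (4.79 ± 0.43), Ankrd23 (4.49 ± 0.29), Kcne1 (4.49 ± 0.52), Thbs4 (4.01 ± 0.58) and Nppb. Ankrd23 encodes a stretch-responsive ankyrin repeat protein of the sarcomere, Kcne1 a subunit of a potassium channel, and Thbs4 a thrombospondin of the matrix. The largest falls were those of Scn4b (−2.30 ± 0.25), a subunit of the cardiac sodium channel, Ddit4l2 (−2.25 ± 0.19), Phkg1 (−2.11 ± 0.22), a subunit of phosphorylase kinase, Atp6ap1l (−2.07 ± 0.23) and Adra1d (−2.07 ± 0.26), an alpha-1 adrenergic receptor. Tceal7 averaged 18.9 ± 11.0 normalized counts in sham and 498 ± 134 in banding, and Scn4b averaged 594 ± 218 and 115 ± 18.5 (SD, n = 5 each). As the naming rule required, these 10 genes all had an adjusted p under 0.05 in limma and separated all libraries of both groups.

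Of 14 measured members of the stretch and fetal list at 4 weeks, 11 rose, 1 fell and 2 did not pass. The same numbers rose and fell when adjusted over the list alone (11 and 1). Examples beside Myh7 are Ankrd1 (2.27 ± 0.15), Xirp2 (2.54 ± 0.21) and Acta1 (2.69 ± 0.29), the skeletal actin of the fetal heart. The list was called higher (camera, adjusted p = 4.57e-13; adjusted p = 0.132 with an estimated correlation). Nppa (NM_012612), which encodes the natriuretic peptide ANP, averaged 3769.9 ± 6069.5 in sham and 19773 ± 9232 in banding and rose by 4.67 ± 1.31 (adjusted p = 0.0138). Its sham libraries ran from 76.2 to 14197. Myl7, the myosin light chain of the atria, also differed between them, and its highest value in sham at 4 weeks was 138 times the lowest. Sequencing found Myl7 above 1000 in 7 of the 19 libraries (replicates 1 and 3 of sham at 4 weeks, 1, 2 and 5 of sham at 8 weeks, 2 of banding at 4 weeks and 3 of banding at 8 weeks), called rich in atrial transcripts here. In these 7 Myl7 ran from 1006 in replicate 2 of sham at 8 weeks to 17580 in replicate 1 of that group. Replicate 3 of banding at 4 weeks lay under the limit at 743, so the limit cuts through a range of values. With edgeR the Nppa change was 2.38 (adjusted p = 0.176) and with DESeq2 2.39 (adjusted p = 0.16), and with the atrial score as a covariate it was 5.29 ± 0.70 (adjusted p = 7.5e-06). That last fit takes 1 slope on the score for all groups, while Nppa ranged 186-fold within sham and 3.48-fold within banding. Among libraries with Myl7 at or under 1000, Nppa lay between 76.2 and 408 in sham (n = 3) and between 7878 and 27403 in banding (n = 4).

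Fatty acid oxidation, the tricarboxylic acid cycle and the respiratory chain were tested as 3 lists at 4 weeks. In fatty acid oxidation 24 of 30 members fell and 0 rose (25 and 0 adjusted over the list alone), among them Hadh (−1.18 ± 0.10), Acsl1 (−0.68 ± 0.07) and Eci1 (−0.67 ± 0.08), and the list was called lower. The camera test of this list gave adjusted p = 1.87e-16 (adjusted p = 0.224 with an estimated correlation). Hadh, an enzyme of the fatty acid spiral, averaged 2112 ± 172 in sham and 933 ± 83.3 in banding. In the tricarboxylic acid cycle 7 of 20 members fell and 0 rose (9 and 0 adjusted over the list alone), with Sdha at −0.37 ± 0.07 and Sucla2 at −0.31 ± 0.07. As a list they were called at an adjusted p of 0.000596 by camera (adjusted p = 0.656 with an estimated correlation). In the nuclear-encoded respiratory chain 11 of 31 members fell and 0 rose (16 and 0 adjusted over the list alone), with Ndufs7 at −0.51 ± 0.09 and Atp5f1a at −0.39 ± 0.08. Camera gave the list an adjusted p of 2.75e-06 (adjusted p = 0.633 with an estimated correlation).

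Matrix genes changed in part at 4 weeks. Of 39 members 11 rose and 1 fell (15 and 2 adjusted over the list alone), including Ccn2 (1.74 ± 0.24), Col8a1 (2.04 ± 0.29) and Cilp (2.19 ± 0.31), and the list was called higher. Tested as a whole, the list had a camera adjusted p of 0.00134 (adjusted p = 0.75 with an estimated correlation). Postn, which encodes periostin of activated fibroblasts, rose by 1.82 ± 0.35 (adjusted p = 0.000635). The fibrillar collagens Col1a1 (−0.21 ± 0.25, adjusted p = 0.623) and Col3a1 (−0.23 ± 0.18, adjusted p = 0.42) did not pass, and the sign of Col1a1 turned to 0.06 without replicate 3 of sham at 4 weeks (adjusted p = 0.888). Without the 7 libraries rich in atrial transcripts Col1a1 had 0.21 (adjusted p = 0.519) and Col3a1 had 0.068 (adjusted p = 0.776). Macrophage markers rose in 10 of 16 cases and fell in 0 (13 and 0 adjusted over the list alone), with Gpnmb at 1.95 ± 0.14, Lyz2 at 0.92 ± 0.14 and Trem2 at 1.75 ± 0.32. For the whole list the camera adjusted p was 5.26e-07 (adjusted p = 0.452 with an estimated correlation).

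In the oxidative stress list 7 of 16 members rose and 1 fell at 4 weeks (7 and 1 adjusted over the list alone), with Maoa at 1.45 ± 0.17, Hmox1 at 1.23 ± 0.20 and Gclc at 0.77 ± 0.13. The list passed camera at an adjusted p of 0.00304 (adjusted p = 0.14 with an estimated correlation). Maoa encodes monoamine oxidase A, an enzyme that releases hydrogen peroxide, and Hmox1 encodes heme oxygenase. Among ion channels and gap junctions 6 of 20 members fell and 1 rose (6 and 1 adjusted over the list alone), with the potassium channels Kcnd2 at −1.99 ± 0.25 and Kcnj3 at −0.90 ± 0.16, and Hcn2 at 0.58 ± 0.11. By camera the list had an adjusted p of 0.028 (adjusted p = 0.452 with an estimated correlation). Cell cycle genes rose in 3 of 31 cases and fell in 0 by limma, and 0 passed when adjusted over the list alone. At an unadjusted p under 0.05, 7 rose, and with edgeR 3 rose and with DESeq2 4. The cell cycle list was called higher (camera, adjusted p = 0.00821; adjusted p = 0.759 with an estimated correlation). Mcm6, a part of the replication helicase, had 0.63 ± 0.19 (adjusted p = 0.0202), and it had 0.58 without replicate 2 of sham (adjusted p = 0.0545), 0.48 without replicate 1 of banding (0.0737) and 0.60 without replicate 5 of banding (0.0514). The cell cycle list had an adjusted p of 0.105 without the 7 libraries rich in atrial transcripts.

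By limma, 2086 of 10926 genes were called at 4 weeks, 1013 higher and 1073 lower, and 337 of them changed at least 2-fold, 155 up and 182 down. The authors' deposited DESeq2 table called 2223 IDs for this comparison, 1073 higher and 1150 lower in banding. Of its 2175 calls among the IDs tested here, 2021 were shared in the same direction. Atp2a2 (−0.73 ± 0.15), which encodes the calcium pump SERCA2, was measured through a single non-coding ID.

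**Figure D1:**
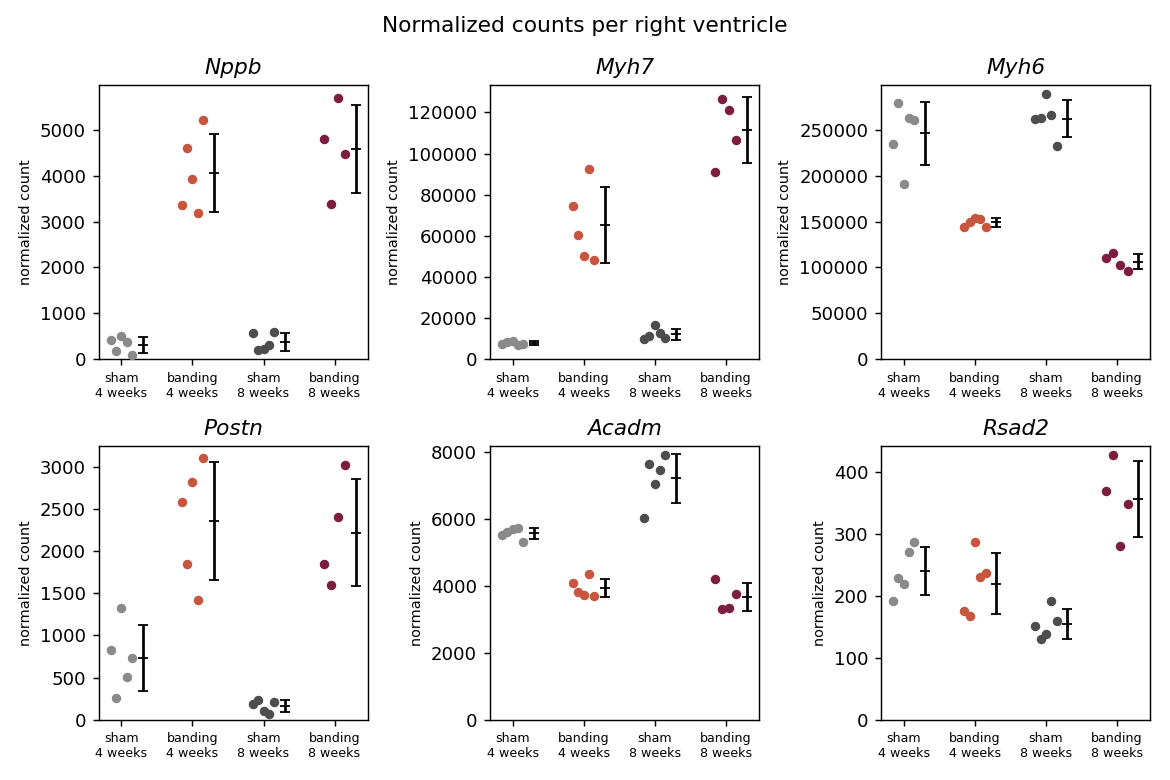
Normalized counts (vertical axes, linear from 0) of 6 genes in each library of the 4 groups, with points for libraries and bars for the mean ± SD. Nppb lay between 85.9 and 591 in all sham libraries and between 3181 and 5701 in all banding libraries, while Rsad2 lay between 280 and 427 in banding at 8 weeks and between 130 and 287 in the other groups.

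The comparison at 8 weeks asked what the same operation showed after more time. Banded ventricles again held more Nppb (4587 ± 960.2 against 375 ± 195, n = 4 and 5; log2 3.75 ± 0.40) and Myh7 (111400.2 ± 15949.5 against 12045 ± 2739; 3.22 ± 0.17). Myh6 fell by 1.30 ± 0.13 (adjusted p = 7e-08 in limma), from 262327.2 ± 20436 to 106335.7 ± 8309.5. Postn rose from 163 ± 71.8 to 2220.1 ± 634, by 3.85 ± 0.37 (adjusted p = 5.36e-08), and 26 of 39 measured matrix genes rose. In fatty acid oxidation 29 of 30 genes fell, in the tricarboxylic acid cycle 19 of 20 and in the respiratory chain 29 of 31, while 9 of 15 interferon response genes and 13 of 16 macrophage markers rose.

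The largest rises at 8 weeks among the genes that met the naming rule were those of Ankrd23 (5.29 ± 0.31), Tceal7 (5.14 ± 0.46), Thbs4 (4.55 ± 0.61), Bex1 (4.11 ± 0.25) and Kcne1 (3.96 ± 0.55). The largest falls under this rule were those of Fam81a (−2.87 ± 0.23), Lsamp (−2.79 ± 0.21), Adra1d (−2.74 ± 0.28), Atp6ap1l (−2.74 ± 0.25) and Angpt1 (−2.72 ± 0.23), the ligand of the endothelial receptor Tie2. Angpt1 averaged 558 ± 216 in sham and 79.9 ± 16.4 in banding, and Ankrd23 averaged 86.3 ± 13.5 and 3468 ± 912. As the same rule required, each of these 10 genes had an adjusted p under 0.05 in limma.

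In the stretch and fetal list 11 of 14 members rose and 2 fell at 8 weeks (11 and 2 adjusted over the list alone), with Xirp2 at 3.08 ± 0.22, Ankrd1 at 2.18 ± 0.16 and Acta1 at 3.68 ± 0.31. The camera test of this list gave adjusted p = 2.26e-08 (adjusted p = 0.14 with an estimated correlation). Nppa rose by 4.15 ± 1.39 (adjusted p = 0.0243) between sham libraries of 126 to 30976 and banding libraries of 22747 to 34942. Its adjusted p was 0.0742 without replicate 3 of sham (log2 3.38), 0.0762 without replicate 4 of sham (3.25), 0.052 without replicate 4 of banding (4.03) and 0.0521 without replicate 5 of banding (4.10), 0.0701 in a robust fit, 0.272 with edgeR (1.80) and 0.296 with DESeq2 (1.80). With the atrial score as a covariate Nppa rose by 5.95 ± 0.78 (adjusted p = 2.71e-06). The highest Myl7 value among sham libraries at 8 weeks was 428 times the lowest. Adult sarcomere and calcium handling genes fell in 7 of 17 cases and rose in 1 (7 and 1 adjusted over the list alone), with Tnni3, the adult cardiac troponin I, at −0.84 ± 0.10 and Atp2a2 at −0.84 ± 0.16. As a list they were called at an adjusted p of 0.028 by camera (adjusted p = 0.688 with an estimated correlation).

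Matrix genes rose in 26 of 39 cases and fell in 1 at 8 weeks (27 and 1 adjusted over the list alone), with Col4a1, a basement membrane collagen, at 0.83 ± 0.08 and Ccn2 at 2.58 ± 0.26 beside Postn. Camera gave the list an adjusted p of 7.23e-12 (adjusted p = 0.452 with an estimated correlation). Col1a1 (0.67 ± 0.26, adjusted p = 0.056) and Col3a1 (0.31 ± 0.19, adjusted p = 0.225) did not pass. In TGF-beta signalling 10 of 19 members rose and 4 fell (11 and 4 adjusted over the list alone), with the ligand Tgfb2 at 3.20 ± 0.26 and the activin subunits Inhba at 1.64 ± 0.19 and Inhbb at 1.75 ± 0.24. Tested as a whole, the list had a camera adjusted p of 0.0123 (adjusted p = 0.59 with an estimated correlation).

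In fatty acid oxidation 29 of 30 members fell and 0 rose at 8 weeks (29 and 0 adjusted over the list alone), with Hadh at −1.58 ± 0.11, Acsl1 at −1.09 ± 0.08 and Hadha at −0.90 ± 0.07. For the whole list the camera adjusted p was 1.67e-22 (adjusted p = 0.14 with an estimated correlation). In the tricarboxylic acid cycle 19 of 20 fell and 0 rose (19 and 0 adjusted over the list alone), with Suclg1 at −0.72 ± 0.08 and Cs, citrate synthase, at −0.54 ± 0.07. The list passed camera at an adjusted p of 2.19e-11 (adjusted p = 0.406 with an estimated correlation). In the nuclear-encoded respiratory chain 29 of 31 fell and 0 rose (29 and 0 adjusted over the list alone), with Ndufs7 at −0.72 ± 0.09 and Atp5f1c at −0.66 ± 0.08. By camera the list had an adjusted p of 5.27e-14 (adjusted p = 0.452 with an estimated correlation). Ion channels and gap junctions fell in 10 of 20 cases and rose in 2 (10 and 2 adjusted over the list alone), with Kcnj3 at −1.29 ± 0.17, Kcnd2 at −1.82 ± 0.26 and Hcn2 at 0.75 ± 0.12. That list had an adjusted p of 0.0353 by camera (adjusted p = 0.452 with an estimated correlation), of 0.0622 with a minimum mean of 50 and of 0.0781 with the atrial score as a covariate.

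Interferon response genes rose in 9 of 15 cases and fell in 0 at 8 weeks (9 and 0 adjusted over the list alone), with the antiviral gene Rsad2 at 1.20 ± 0.16, Dhx58 at 1.17 ± 0.21 and Ifi27 at 0.65 ± 0.11. The camera test of this list gave adjusted p = 0.00025 (adjusted p = 0.567 with an estimated correlation). At 4 weeks 0 of the 15 passed with limma, 2 were lower at an unadjusted p under 0.05, and 0 passed with edgeR and 1, lower, with DESeq2. The interferon list was not called at 4 weeks (camera, adjusted p = 0.151). Macrophage markers rose in 13 of 16 cases and fell in 0 (14 and 0 adjusted over the list alone), with Gpnmb at 2.41 ± 0.15, Lyz2 at 1.43 ± 0.15 and Csf1r at 0.80 ± 0.13. As a list they were called at an adjusted p of 9.57e-07 by camera (adjusted p = 0.452 with an estimated correlation).

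Markers of vessel cells also rose in part at 8 weeks. Endothelial markers rose in 7 of 17 cases and fell in 1 (8 and 1 adjusted over the list alone), with Eng at 0.84 ± 0.11 and Cd34 at 0.56 ± 0.08. Camera gave the list an adjusted p of 0.00635 (adjusted p = 0.59 with an estimated correlation). Smooth muscle and pericyte markers rose in 6 of 14 cases and fell in 0 (6 and 0 adjusted over the list alone), with Cspg4 at 0.95 ± 0.12 and Pdgfrb at 0.76 ± 0.10. Tested as a whole, the list had a camera adjusted p of 0.0319 (adjusted p = 0.592 with an estimated correlation). Cell cycle genes rose in 9 of 31 cases and fell in 1 (9 and 1 adjusted over the list alone), with Mcm6 at 0.94 ± 0.20 and Aurkb at 1.55 ± 0.33. For the whole list the camera adjusted p was 0.0165 (adjusted p = 0.765 with an estimated correlation). The cell cycle list had an adjusted p of 0.0866 with the atrial score as a covariate, and Aurkb had 0.92 ± 0.33 (adjusted p = 0.0536) without the 7 libraries rich in atrial transcripts.

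Red blood cell markers rose in 4 of 6 cases and fell in 0 at 8 weeks (6 and 0 adjusted over the list alone), with Alas2, the heme synthesis enzyme of red cell precursors, at 1.74 ± 0.36 and Hbb at 1.74 ± 0.37. The list passed camera at an adjusted p of 0.00679 (adjusted p = 0.59 with an estimated correlation). Hbb lay between 7219 and 10660 in replicates 1, 3 and 5 of banding at 8 weeks and at 2082 in replicate 4. Without the 7 libraries rich in atrial transcripts the list had an adjusted p of 0.0906, Alas2 had 1.21 ± 0.45 (adjusted p = 0.066) and Hbb 1.18 ± 0.43 (adjusted p = 0.0561).

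At 8 weeks, 3644 genes were called by limma, 1830 higher and 1814 lower, and 733 changed at least 2-fold, 420 up and 313 down. The authors' deposited DESeq2 table called 3561 IDs, 1809 higher and 1752 lower. Of its 3481 calls among the IDs tested here, 3404 were shared in the same direction. In the authors' tables that cross age with operation, 2784 IDs were called between banding at 8 weeks and sham at 4 weeks (1408 higher and 1376 lower in banding) and 3814 between banding at 4 weeks and sham at 8 weeks (1894 higher and 1920 lower in banding).

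**Figure D2:**
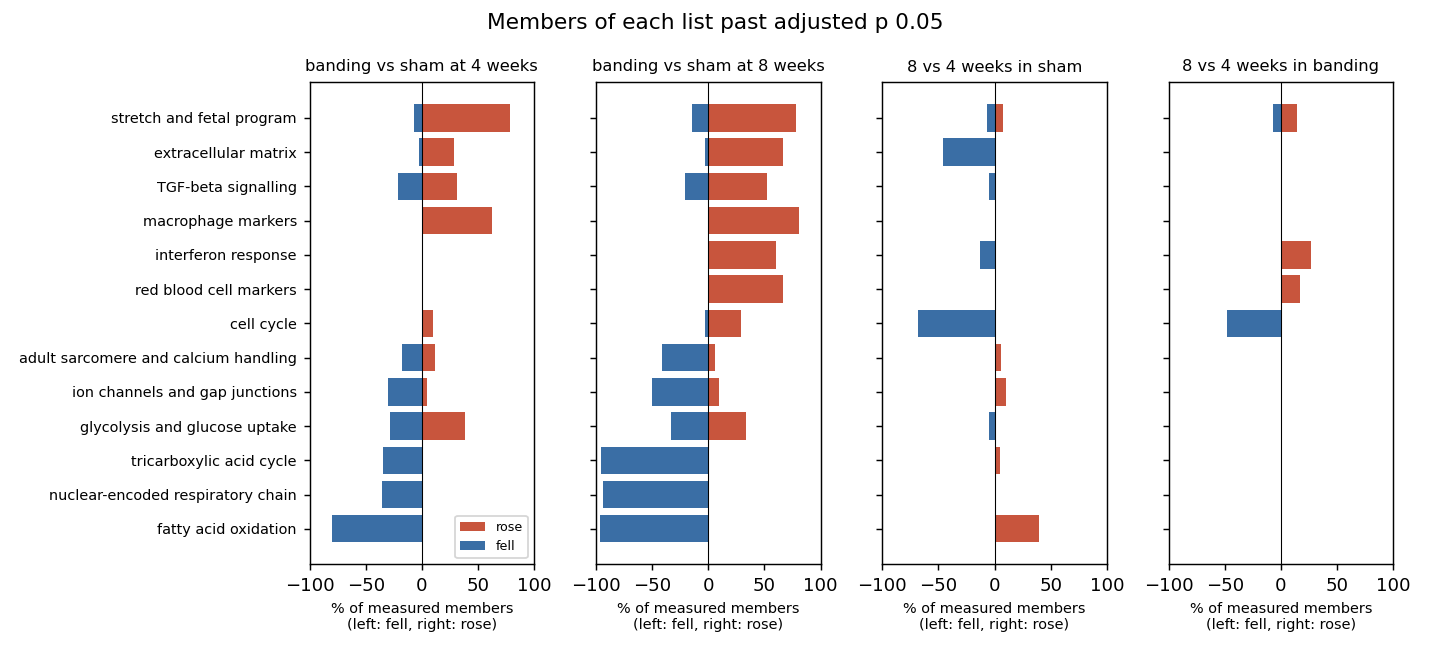
Share of the measured members of 13 lists (horizontal axes, percent) that rose (right) or fell (left) at a limma adjusted p under 0.05, with 1 panel for each of 4 comparisons. In fatty acid oxidation 24 of 30 members fell with banding at 4 weeks and 29 of 30 at 8 weeks, and 12 rose with time in sham.

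Whether the same genes moved at both times was asked across genes, with comparisons that share no libraries. Genes called at both times numbered 1653, and 1650 of them moved the same way, 790 up, such as Nppb, Myh7, Thbs4 and Gpnmb, and 860 down, such as Hadh, Acsl1, Adra1d and Kcnd2. Independent lists of these sizes would share 169.7 rising and 178.1 falling genes. Both comparisons took the spread of each gene from 1 model, so these numbers can understate the overlap without a shared effect. The log2 fold changes at both times correlated across genes with Pearson's r = 0.797 and Spearman's rho = 0.698, where genes are not independent replicates. Among genes called at both times, the effect at 8 weeks rose by 1.21 per unit of the effect at 4 weeks. Of 433 genes called at 4 weeks alone, 394 had the same sign at 8 weeks, and of 1991 called at 8 weeks alone, 1788 had the same sign at 4 weeks.

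**Figure D3:**
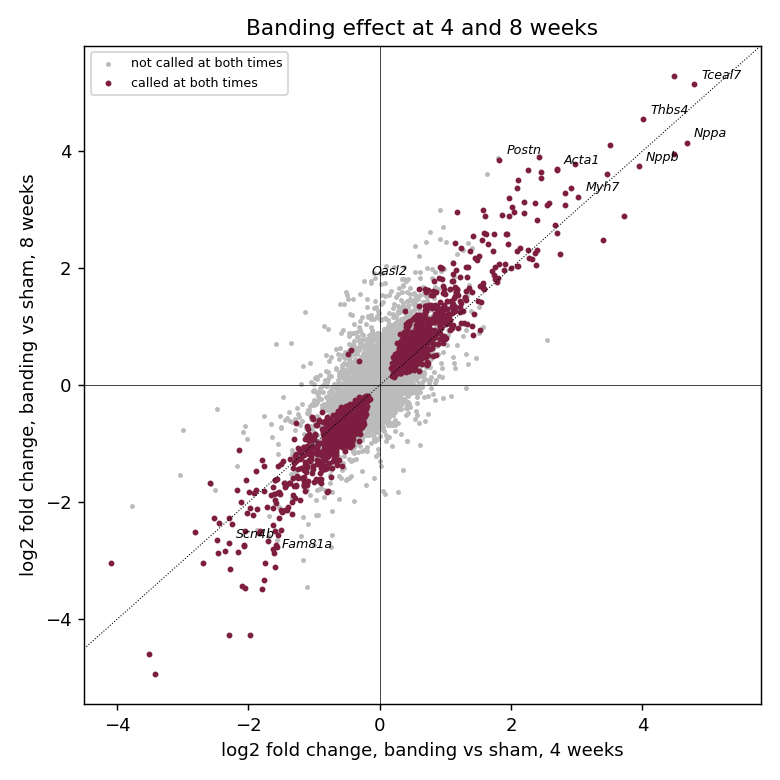
Log2 fold change of banding against sham at 4 weeks (horizontal axis) and at 8 weeks (vertical axis), with 1 point per gene and genes called at both times in color. Pearson's r was 0.797 across genes, and 1650 of the 1653 genes called at both times had the same direction.

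Growth and age without a band were described by sham ventricles at 8 against 4 weeks. Of 31 cell cycle genes 21 fell, and of 39 matrix genes 18 fell. Top2a, a topoisomerase of dividing cells, averaged 322 ± 119 at 4 weeks and 109 ± 11.6 at 8 weeks (n = 5 each) and fell by 1.49 ± 0.19 (limma, adjusted p = 8.57e-05). Tnc, a matrix protein of developing tissue, fell by 1.96 ± 0.22 (adjusted p = 2.44e-05), from 141 ± 24.4 to 35.7 ± 8.35. In fatty acid oxidation 12 of 30 genes rose.

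The largest falls with time in sham under the naming rule were those of Postn (−2.11 ± 0.35), Tnc, Kif11 (−1.70 ± 0.21), Ect2 (−1.67 ± 0.26) and Eln (−1.65 ± 0.36), which encodes elastin. The largest rises were those of Fmo2 (1.36 ± 0.20), Fkbp5 (1.20 ± 0.16), a target of glucocorticoids, Sult1a1 (1.10 ± 0.26), Fmo1 (1.06 ± 0.16) and Lrrc2 (1.05 ± 0.16). Cell cycle genes fell in 21 of 31 cases and rose in 0 (29 and 0 adjusted over the list alone), with Kif11, Top2a and Cenpf (−1.63 ± 0.21) as examples. By camera the list had an adjusted p of 3.78e-27 (adjusted p = 0.14 with an estimated correlation). Matrix genes fell in 18 of 39 cases and rose in 0 (26 and 0 adjusted over the list alone), with Col4a1 at −0.63 ± 0.08 and Mmp14 at −0.85 ± 0.12. The camera test of this list gave adjusted p = 1.44e-20 (adjusted p = 0.298 with an estimated correlation). Fatty acid oxidation genes rose in 12 of 30 cases and fell in 0 (20 and 0 adjusted over the list alone), with Decr1 at 0.48 ± 0.09 and Acadm at 0.37 ± 0.08. As a list they were called at an adjusted p of 5.56e-13 by camera (adjusted p = 0.298 with an estimated correlation).

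Fewer members of other lists passed with time in sham. Endothelial markers fell in 4 of 17 cases and rose in 1 (4 and 1 adjusted over the list alone), with Cd34 at −0.40 ± 0.07 and Flt1 at 0.35 ± 0.07 (camera, lower, adjusted p = 0.00304; adjusted p = 0.556 with an estimated correlation). Fibroblast markers fell in 4 of 13 cases and rose in 1 (4 and 1 adjusted over the list alone), with Thy1 at −1.29 ± 0.27. Camera gave the list an adjusted p of 0.00679 (adjusted p = 0.624 with an estimated correlation). Interferon response genes fell in 2 of 15 cases, for example Rsad2 (−0.63 ± 0.15), and rose in 0 (6 and 1 adjusted over the list alone; camera, lower, adjusted p = 0.00635; adjusted p = 0.633 with an estimated correlation). Adult sarcomere genes rose in 1 of 17 cases, Ryr2 (0.33 ± 0.08), the calcium release channel, and fell in 0 (5 and 0 adjusted over the list alone; camera, adjusted p = 0.0024; adjusted p = 0.592 with an estimated correlation). In the oxidative stress list Cat, catalase, rose (0.35 ± 0.06) and 1 member fell (6 and 1 adjusted over the list alone; camera, higher, adjusted p = 0.0319; adjusted p = 0.224 with an estimated correlation). Ion channels rose in 2 of 20 cases and fell in 0 (2 and 0 adjusted over the list alone), with Kcnj11 at 0.37 ± 0.08. Tested as a whole, the list had a camera adjusted p of 0.0261 (adjusted p = 0.452 with an estimated correlation).

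Further lists were called with time in sham on small shifts of many members. In the tricarboxylic acid cycle 1 of 20 members rose, and 0 passed when adjusted over the list alone (camera, higher, adjusted p = 6.69e-06; adjusted p = 0.59 with an estimated correlation). Of 31 respiratory chain genes 0 passed either way in limma, 4 rose at an unadjusted p under 0.05, and 0 passed with edgeR and DESeq2 (camera, higher, adjusted p = 0.000881; adjusted p = 0.75 with an estimated correlation). Of 16 macrophage markers 0 passed either way in limma, 2 fell at an unadjusted p under 0.05, and 0 passed with edgeR and 1 with DESeq2 (camera, lower, adjusted p = 0.0271; adjusted p = 0.754 with an estimated correlation). After quantile normalization the respiratory chain had an adjusted p of 0.709, the adult sarcomere list 0.376 and the oxidative stress list 0.0914. The oxidative stress list had 0.0676 with a minimum mean of 50, and the interferon list had 0.0736 without the 7 libraries rich in atrial transcripts.

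With time in sham, 714 genes were called by limma, 292 higher and 422 lower, and 126 changed at least 2-fold, 15 up and 111 down. The authors' deposited table called 957 IDs, 431 higher and 526 lower at 8 weeks. Of its 956 calls among the IDs tested here, 696 were shared in the same direction. The count was 423 without replicate 3 of sham at 4 weeks, 462 without replicate 2 and 443 without replicate 3 of sham at 8 weeks, and 157 without the 7 libraries rich in atrial transcripts. In that last fit, of 12 libraries, Decr1 (0.44), Acadm (0.39), Cd34 (−0.37), Thy1 (−1.05), Ryr2 (0.36), Cat (0.33), Kcnj11 (0.40), Sult1a1 (1.37) and Rsad2 (−0.68) kept their direction and no longer passed.

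In banded ventricles fewer genes passed between 4 and 8 weeks. Of 31 cell cycle genes 15 fell from 4 to 8 weeks, and 4 of 15 interferon response genes rose. Top2a averaged 392 ± 122 at 4 weeks (n = 5) and 148 ± 14.9 at 8 weeks (n = 4) and fell by 1.36 ± 0.20 (limma, adjusted p = 0.00279). The interferon-inducible gene Ifi27l2b rose by 0.88 ± 0.15 (adjusted p = 0.00963), and Maoa rose by 0.95 ± 0.18 (adjusted p = 0.0166), from 4099 ± 391 to 8166 ± 2400.3.

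Cell cycle genes fell in 15 of 31 cases and rose in 0 with time in banding (26 and 0 adjusted over the list alone), with Bub1 at −1.17 ± 0.17 and Cenpf at −1.31 ± 0.22 beside Top2a. For the whole list the camera adjusted p was 2.04e-31 (adjusted p = 0.14 with an estimated correlation). Interferon response genes rose in 4 of 15 cases and fell in 0 (11 and 0 adjusted over the list alone), with Ifit3 at 1.35 ± 0.28. The list passed camera at an adjusted p of 6.97e-12 (adjusted p = 0.204 with an estimated correlation). The adjusted p of Ifit3 was 0.0196, and it had 1.15 without replicate 1 of banding at 4 weeks (adjusted p = 0.0534), 1.09 without replicate 1 of banding at 8 weeks (0.0647) and 1.40 without the libraries rich in atrial transcripts (0.0802). Among red blood cell markers 1 of 6 rose and 0 fell (6 and 0 adjusted over the list alone), and Alas2 had 1.44 ± 0.36 (adjusted p = 0.0508; camera for the list, adjusted p = 3.8e-07; adjusted p = 0.263 with an estimated correlation). Alas2 lay between 581 and 896 in replicates 1, 3 and 5 of banding at 8 weeks and at 141 in replicate 4.

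Energy genes were called as lists with time in banding while single members did not pass in limma over all genes. Fatty acid oxidation was lower with 0 of 30 members passing, 1 falling when adjusted over the list alone and 3 at an unadjusted p under 0.05. By camera the list had an adjusted p of 0.00277 (adjusted p = 0.66 with an estimated correlation). The tricarboxylic acid cycle was lower with 0 of 20 passing, 1 falling when adjusted over the list alone and 4 at an unadjusted p under 0.05. The camera test of this list gave adjusted p = 2.24e-05 (adjusted p = 0.594 with an estimated correlation). The respiratory chain was lower with 0 of 31 passing either way and 6 falling at an unadjusted p under 0.05 (camera, adjusted p = 6.54e-08; adjusted p = 0.592 with an estimated correlation). Glycolysis was lower with 0 of 21 passing either way and 5 falling at an unadjusted p under 0.05 (camera, adjusted p = 0.0103; adjusted p = 0.594 with an estimated correlation). In these 4 lists edgeR called 0 members, and DESeq2 called 1 in each of the first 2 and 0 in the others. Immediate early genes were higher with 0 of 21 passing either way in limma, at an unadjusted p under 0.05, or in edgeR and DESeq2. As a list they were called at an adjusted p of 0.0169 by camera (adjusted p = 0.765 with an estimated correlation). Without the 7 libraries rich in atrial transcripts, fatty acid oxidation had an adjusted p of 0.213 and glycolysis of 0.165.

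With time in banding, 125 genes were called by limma, 53 higher and 72 lower, and 51 changed at least 2-fold, 9 up and 42 down. The authors' deposited table called 271 IDs, 134 higher and 137 lower at 8 weeks. Of its 270 calls among the IDs tested here, 124 were shared in the same direction. The count was 38, 69 and 39 without replicates 1, 2 and 5 of banding at 4 weeks, 68, 46 and 81 without replicates 1, 3 and 5 of banding at 8 weeks, 64 with no filter, 50 without the libraries rich in atrial transcripts and 298 with the atrial score as a covariate.

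Whether the banding effect itself differed between 8 and 4 weeks was tested as a difference of both effects. Rsad2 and Oasl2, antiviral genes induced by interferon, and Fxyd6, a regulator of the sodium pump, passed with a higher banding effect at 8 weeks. Chance could not be excluded for these 3 calls, since 6 of 100 reassignments of the times, the real one included, gave as many. Rsad2 (NM_138881) averaged 239.6 in sham (192 to 287 in the 5 libraries) and 219.7 ± 48.9 in banding at 4 weeks, and 154 ± 23.7 in sham and 356 ± 60.7 in banding at 8 weeks, a difference of 1.34 ± 0.21. Fxyd6 (NM_022005) averaged 239 ± 25.4, 312 ± 15.2, 136 ± 14.4 and 329 ± 42.2 in the same order, a difference of 0.87 ± 0.14. Oasl2 (NM_001009682), named here after its values were seen because its mean lies under 50, averaged 43.9 ± 8.61, 37.7 ± 11.1, 25.0 ± 5.95 and 87.8 ± 16.9, a difference of 2.02 ± 0.31. These 3 genes were all that limma called, each at an adjusted p of 0.0101, and 1278 genes had an unadjusted p under 0.05.

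At the preset correlation camera called several lists different in effect between both times, largely through members that did not pass alone. With an estimated correlation it called 0 of them. Interferon response genes had a higher effect at 8 weeks, with 1 of 15 members higher, and 11 adjusted over the list alone. Camera gave the list an adjusted p of 5.27e-14 (adjusted p = 0.149 with an estimated correlation). Fatty acid oxidation had a more negative effect at 8 weeks (median log2 −0.901, against −0.499 at 4 weeks). Its median change from 4 to 8 weeks was 0.256 in sham and −0.114 in banding. Of its 30 members 0 passed in limma and edgeR, 7 were lower in DESeq2 and 18 were lower when adjusted over the list alone (camera, adjusted p = 1.88e-18; adjusted p = 0.202 with an estimated correlation), for example Hadha at −0.44 ± 0.10 (adjusted p = 0.0703). The tricarboxylic acid cycle also had a more negative effect at 8 weeks (median −0.465, against −0.156 at 4 weeks). Its median change with time was 0.155 in sham and −0.133 in banding. Of its 20 members 0 passed in limma and edgeR, 2 were lower in DESeq2 and 10 were lower when adjusted over the list alone. Tested as a whole, the list had a camera adjusted p of 3.89e-13 (adjusted p = 0.321 with an estimated correlation). The respiratory chain had a more negative effect at 8 weeks as well (median −0.432, against −0.188 at 4 weeks). Its median change with time was 0.129 in sham and −0.155 in banding. Of its 31 members 0 passed either way in limma or in edgeR and DESeq2, and 15 were lower at an unadjusted p under 0.05. For the whole list the camera adjusted p was 3.93e-13 (adjusted p = 0.452 with an estimated correlation). Matrix genes had a higher effect, with 0 of 39 passing in limma and edgeR, 2 higher in DESeq2 and 13 higher when adjusted over the list alone (camera, adjusted p = 1.28e-14; adjusted p = 0.422 with an estimated correlation), for example Postn at 2.04 ± 0.51 (adjusted p = 0.118) and Tnc at 1.39 ± 0.32 (adjusted p = 0.0786). The median log2 change of the 39 from 4 to 8 weeks was −0.667 in sham and −0.05 in banding. In banding 0 passed in limma and edgeR, 2 rose and 8 fell at an unadjusted p under 0.05, 3 fell in DESeq2 and 7 fell when adjusted over the list alone (camera, adjusted p = 0.131). Red blood cell markers had a higher effect, with 0 of 6 passing in limma and edgeR, 2 higher in DESeq2 and 5 higher when adjusted over the list alone (camera, adjusted p = 1.79e-06; adjusted p = 0.298 with an estimated correlation).

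Other lists with a higher effect of banding at 8 weeks were TGF-beta signalling (camera, adjusted p = 0.00304; adjusted p = 0.452 with an estimated correlation), fibroblast markers (adjusted p = 0.000928; adjusted p = 0.59 with an estimated correlation), endothelial markers (adjusted p = 0.00901; adjusted p = 0.59 with an estimated correlation), smooth muscle and pericyte markers (adjusted p = 0.0108; adjusted p = 0.55 with an estimated correlation), inflammatory cytokines (adjusted p = 0.0169; adjusted p = 0.633 with an estimated correlation) and macrophage markers (adjusted p = 0.0227; adjusted p = 0.75 with an estimated correlation). Adult sarcomere genes (camera, adjusted p = 0.00415; adjusted p = 0.614 with an estimated correlation) and glycolysis (camera, adjusted p = 0.00415; adjusted p = 0.59 with an estimated correlation) had a negative difference of effects. The median log2 effect of banding was −0.101 at 4 weeks and −0.184 at 8 weeks in the adult sarcomere list, and 0.195 and 0.018 in glycolysis. In these 8 lists 0 members passed in limma over all genes and with edgeR, and DESeq2 called 1 member in each of the TGF-beta, endothelial and adult sarcomere lists. Adjusted over the list alone 3 of 19 TGF-beta genes and 1 endothelial marker were higher and 1 adult sarcomere gene was lower. The adult sarcomere list had an adjusted p of 0.0831 after quantile normalization, and without the 7 libraries rich in atrial transcripts glycolysis had 0.169 and inflammatory cytokines 0.388.

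The number of genes with a different effect depended on the fit. It was 3 with limma and with edgeR, 89 with DESeq2, 6 after quantile normalization and 145 with the atrial score as a covariate. Single libraries also moved it. The count was 5 and 23 without replicates 1 and 2 of sham at 4 weeks, 23, 5 and 7 without replicates 1, 4 and 5 of sham at 8 weeks, 19 without replicate 3 of banding at 4 weeks, and 16, 9 and 15 without replicates 1, 3 and 4 of banding at 8 weeks. Fxyd6 had 0.82 (adjusted p = 0.0509) without replicate 5 of banding at 8 weeks, which left 2 genes, and Rsad2 had 1.20 (adjusted p = 0.164) without the 7 libraries rich in atrial transcripts, which also left 2.

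**Figure D4:**
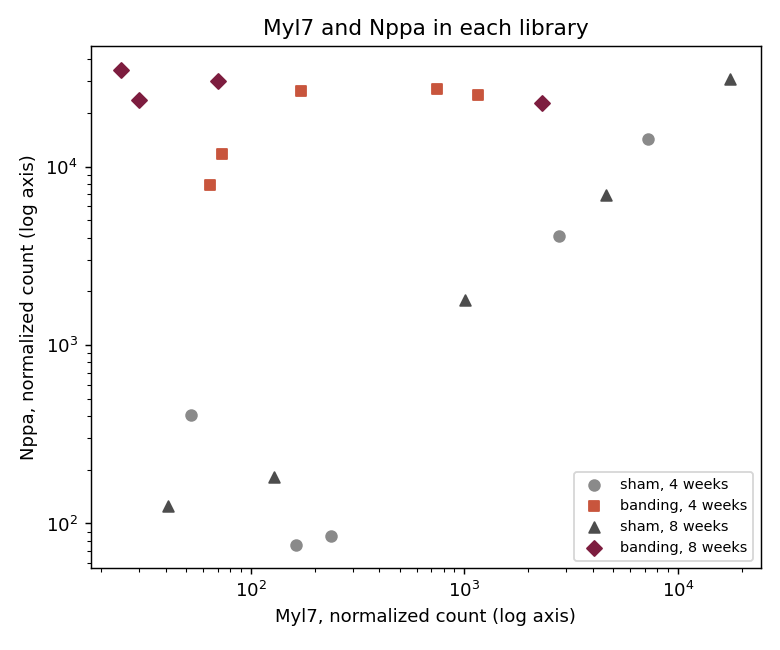
Normalized counts of Myl7 (horizontal axis, log scale) and Nppa (vertical axis, log scale) in each of the 19 libraries, with 1 symbol per group. Myl7 exceeded 1000 in 7 libraries, and within sham at 8 weeks Nppa ran from 126 to 30976.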

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

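The tests of atrial transcripts and of the covariate in this part were chosen only after the results were seen, and the count of other splits of the samples was planned.

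Atrial transcripts differed widely between libraries of the same group: Myl7 exceeded 1000 in 5 of 10 sham and 2 of 9 banding libraries (Fisher's exact test, 2-sided p = 0.35), reached 17580 in replicate 1 of sham at 8 weeks, and Nppa went with it in sham, from 76.2 to 14197 at 4 weeks and from 126 to 30976 at 8 weeks. So few libraries cannot show that the groups were balanced. At 8 weeks Myl7 exceeded 1000 in 3 of 5 sham and 1 of 4 banding libraries. The median log2 effect of banding on the atrial list, not called at either time, was −0.259 at 4 weeks and −1.257 at 8 weeks. Within a sham group, where operation and time are equal, the highest Myl7 was at least 138 times the lowest, but this is the spread to be explained, so a response to the operation or the time that differs between animals stays open. A candidate explanation is atrial and fat tissue collected with some ventricles: 7 of 8 other members of the atrial list rose with Myl7 within groups (1-sided permutation test with 10000 shuffles, adjusted over the 8), with slopes on the log2 scale of 0.91 for Myl4, 0.95 for Sln, 1.10 for Bmp10 and 1.05 for Mybphl, but 0.19 for Stard10, 0.10 for Nr2f2 and 0.05 for Dkk3, and 0.03 for Nr2f1, which did not pass. An earlier form of this test, a comparison of libraries above and under the Myl7 limit, found 5 of the 8 higher in all 4 groups, short of the 6 set as needed. It was replaced by the slopes, which also rank libraries by Myl7. The 7 of 8 thus come from a second test chosen after the data were seen. For fat the 7 markers went apart, with slopes of 0.92 for Adipoq, 0.67 for Plin1, 0.56 for Retn, 0.41 for Pck1, 0.20 for Cfd, 0.00 for Cidea and −0.03 for Fabp4, and atrial gene expression within the ventricle itself stays open, as does any effect of the dissection.

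The number of genes with a different banding effect at 8 and 4 weeks was 3 in limma and 145 once a score of Myl7, Sln and Bmp10 entered as a covariate. The log2 effect at 8 minus that at 4 weeks was positive for 67 of these, such as Fxyd6 (0.82), Mx2 (1.57), Postn (2.22) and Fn1 (1.14). It was negative for 78, such as Hadha (−0.47), Acadvl (−0.46) and Cs (−0.40). By list, it was positive for 7 of 39 matrix genes and 5 of 15 interferon genes. It was negative for 7 of 30 fatty acid oxidation, 7 of 20 tricarboxylic acid cycle and 5 of 31 respiratory chain genes. That any covariate would add such calls is argued against by shuffles of the score within groups, of which 1 of 100, the real one, reached 145 (highest other 61). In the reported fit, without the covariate, 100% of the 145 had the same direction. Their median absolute log2 difference was 0.55 there and 0.60 with the covariate, and their median SE was 0.155 and 0.139. For these 145 genes the values argue against differences made by the covariate itself, since differences of like size were there without it. Both fits hold the same libraries, so the values cannot tell whether these differences would recur in other animals. In the 12 libraries at or under the Myl7 limit 100% also had the same direction without it, against 83% of all genes, but the 145 were chosen in a fit that holds these libraries. Of 100 reassignments of the times within each operation, 1, the real one, reached 145 with the covariate (highest other 6). Without the covariate 6 of 100 reached 3 (highest other 61, a count whose source was not tested), so chance could not be excluded for the 3. Such reassignments also break up any change with time that sham and banding share. They therefore cannot exclude chance for a difference in the banding effect alone, also for the 145. A different banding effect at 8 weeks on these genes stays open, and the covariate was chosen on the same data.

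Without the covariate, the log2 effect of banding at 8 minus that at 4 weeks was 1.34 for Rsad2, 0.87 for Fxyd6 and 2.02 for Oasl2, each past limma's test of the difference at an adjusted p of 0.0101. The remaining values are single libraries far from the others of their group, found among 430 groups of values tested. Chance alone marks about 1 in 20 of such groups, and 19 were found, no more than chance would give.

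Replicate 1 of sham at 8 weeks, the library with the most Myl7, held 5 of them. There Atp5f1c was at 7180 normalized counts (others 8600 to 9240), Ndufs7 at 1990 (2460 to 2630), Ndufs3 at 2940 (3600 to 3830), Kcnj3 at 906 (476 to 554) and Kcnj5 at 791 (349 to 421). In replicate 3 of sham at 4 weeks Kcnj3 was at 261 (433 to 512), Hrc at 1380 (2200 to 2590) and Cspg4 at 1190 (711 to 813). In the other sham libraries Acta1 was at 9290 in replicate 4 at 4 weeks (3940 to 4700), Hbb at 1220 in replicate 1 at 4 weeks (2570 to 3270), Tceal7 at 1.85 in replicate 2 at 8 weeks (15.0 to 22.1) and Mx2 at 214 in replicate 4 at 8 weeks (140 to 154). In banding at 4 weeks Oas1b was at 71.0 in replicate 3 (38.7 to 44.0) and Alas2 at 98.0 in replicate 1 (176 to 220). In banding at 8 weeks Inhba was at 44.1 (60.1 to 61.9) and Pdgfrb at 1700 (1300 to 1350) in replicate 4, Cs at 4600 (4920 to 4960) and Prc1 at 41.6 (86.1 to 95.6) in replicate 3, and Hadhb at 7560 (6170 to 6360) in replicate 1.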

How the results depend on the processing

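The atrial score as a covariate and the fit without the 7 libraries with Myl7 above 1000 were chosen only after the results were seen, and the other alternatives were planned. The counts at 4 and 8 weeks stayed within 1.5 times under every alternative run, from 1682 to 2074 (reported 2086) and from 3076 to 3568 (reported 3644) without single libraries, and genes called both there and in the reported fit had the same direction in both. For each change named here the cause was not tested, except that leaving out 7 libraries leaves 12. The count with time in sham was 157 without those 7 and 423 to 848 without single libraries. The count with time in banding was 64 with no filter, where more genes enter the adjustment, 298 with the covariate, 50 without the 7 libraries, 271 with DESeq2 and 38 to 150 without single libraries. The count of different effects was 6 after quantile normalization, 145 with the covariate, 89 with DESeq2 and 2 to 23 without single libraries. Of 57 list calls, 0 passed with an estimated correlation (lowest adjusted p 0.132). The correlation of both banding effects was 0.809 with a pseudocount of 5, 0.661 with no filter, 0.847 with a minimum mean of 50, 0.770 without the 7 libraries and 0.762 to 0.807 without single libraries. Col1a1 and Col3a1, not called at 4 weeks, turned to 0.21 and 0.068 without the 7 libraries, and Col1a1 ran from −0.43 to 0.058 without single libraries. Among named genes the covariate ended 0 calls and added 36, leaving out the 7 libraries ended 35, and single libraries ended 89 calls and added 48 over all fits. After rescaling the median log2 change of all genes lay within 0.015 of 0 in each comparison.

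With the replicate number as a block the counts were 2068, 3402, 721, 116 and 3, and the list calls 57. Deviations of the 27 pairs of libraries with the same number correlated from −0.276 to 0.323 (median 0.021, against −0.007 for the 108 other pairs), and 6 of 19 libraries correlated best with their own number. These values showed no clear pairing by number and cannot exclude one. Keeping the library GB20 was planned and not run, since no column of the deposited counts carries that name. Genes under the minimum of 10 in 4 libraries were left out of the reported fit at 2.70 to 8.54 M reads, and those with any reads entered the fit with no filter.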

Other observations

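The counts of other splits of the samples in this part were planned, and no test here was chosen after its result was seen. Of 21 measured members of the glycolysis list 8 rose and 6 fell with banding at 4 weeks (9 and 7 adjusted over the list alone), and 7 rose and 7 fell at 8 weeks (7 and 7 adjusted over the list alone), and the list was not called (camera, adjusted p = 0.294 and 0.713). Pfkp, the platelet form of phosphofructokinase, rose by 0.92 ± 0.10 at 4 weeks and 1.04 ± 0.11 at 8 weeks, while Pfkm, the muscle form, fell (−0.59 ± 0.07 and −0.89 ± 0.08). Among 20 neurohormonal genes 4 rose and 6 fell at 4 weeks (4 and 6 adjusted over the list alone) and 7 rose and 7 fell at 8 weeks (7 and 8 adjusted over the list alone; camera, adjusted p = 0.271 and 0.798). Adra1b and Adra1d, alpha-1 adrenergic receptors, fell (−0.94 ± 0.09 and −2.07 ± 0.26 at 4 weeks, −0.99 ± 0.09 and −2.74 ± 0.28 at 8 weeks). In the Schwann cell and neural list 3 of 7 rose and 2 fell at each time (3 and 2 adjusted over the list alone; camera, adjusted p = 0.271 and 0.442), and Ncam1, a neural cell adhesion molecule that muscle can also express, rose by 2.71 ± 0.17 and 3.70 ± 0.18. Of 20 inflammatory genes 2 rose at 4 weeks and 6 at 8 weeks (2 and 6 adjusted over the list alone; camera, adjusted p = 0.521 and 0.0631), and Sele, the endothelial adhesion molecule E-selectin, rose by 1.97 ± 0.27 and 2.89 ± 0.29. Among 19 angiogenic factors 1 rose and 5 fell at 4 weeks (1 and 5 adjusted over the list alone) and 2 rose and 5 fell at 8 weeks (2 and 5 adjusted over the list alone; camera, adjusted p = 0.327 and 0.555), with Angpt1 at −1.58 ± 0.22 and −2.72 ± 0.23 and Egln3 at 0.69 ± 0.11 and 0.75 ± 0.11.

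Other lists were not called in either comparison of banding with sham (camera, adjusted p given for 4 and then 8 weeks). The unfolded protein list had 0.603 and 0.368, and 3 of its 15 members fell at 8 weeks, among them Dnajb9 (−0.55 ± 0.09) and Hspa5 (−0.49 ± 0.09), where 3 also fell when adjusted over the list alone. Adipocyte markers had 0.131 and 0.134, and 2 and 1 of 7 fell (2 and 1 adjusted over the list alone), with Cidea at −0.47 ± 0.10 and −0.66 ± 0.10. Atrial markers had 0.521 and 0.217, and 1 of 9 fell at each time (1 and 1 adjusted over the list alone), Stard10 at −1.36 ± 0.39 and −1.68 ± 0.42. Fibroblast markers had 0.9 and 0.151, and of 13 members 4 rose and 2 fell at 4 weeks (4 and 5 adjusted over the list alone) and 5 rose and 1 fell at 8 weeks (6 and 1 adjusted over the list alone), with Thy1 at 1.42 ± 0.27 and 2.54 ± 0.29 and Pdgfra at −0.76 and −0.57. Lymphocyte markers had 0.493 and 0.935, and Cd4 was at 0.86 ± 0.17 at 8 weeks. Neutrophil and mast cell markers had 0.41 and 0.796. Mesothelial and epicardial markers had 0.603 and 0.6, with Wt1 at 0.91 ± 0.18 at 8 weeks. Clock genes had 0.937 and 0.632, with Cry2 at 0.52 ± 0.09 and 0.26 ± 0.10, and immediate early genes had 0.493 and 0.9. Lists not called at 4 weeks alone were adult sarcomere (0.444), TGF-beta signalling (0.195), endothelial (0.185), smooth muscle and pericyte (0.391), interferon response (0.151) and red blood cell markers (0.739), and the oxidative stress list was not called at 8 weeks alone (0.0881), where Maoa was at 2.18 ± 0.18. Of 2 measured skeletal muscle markers Casq1 rose at both times (1.44 ± 0.24 at 8 weeks) and Atp2a1 was not called, and the Y-linked genes Ddx3y and Eif2s3y of the sex list were not called in any comparison.

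Other splits of the same libraries were drawn to ask whether chance could give as many calls. Chance could be excluded for banding at 4 weeks, where 1 of 100 splits, the real one, reached 2086 (highest other 196), and for banding at 8 weeks (1 of 100 reached 3644, highest other 2556, in a split of 4 sham libraries against the remaining 1 sham and the 4 banding libraries). It could be excluded for time in sham (1 of 100 reached 714, highest other 210) and for time in banding (1 of 100 reached 125, highest other 46).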
